A study of Homo sapiens with 6 samples.

How the data were processed

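Total RNA of Capan-2 cells, a human pancreatic ductal adenocarcinoma line, was labelled with biotin and hybridised to Illumina bead arrays, per the labels. There were 6 arrays, 3 of cells given the vehicle DMSO and 3 of cells given PD-0332991 (palbociclib, an inhibitor of the cyclin-dependent kinases CDK4 and CDK6), with RNA taken at 72 h. The drug concentration is not given in the sources used here. The labels number the replicates 1 to 3 in each group and do not say whether they were separate cultures. The p-values of the probe comparison therefore measure only the spread between these samples, which may be technical.

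The values used were the authors' deposited processed table, which holds 1 intensity per probe and sample on a linear scale. From the values, this table had been quantile-normalized between arrays: after sorting, the 6 columns differ by at most 1.52 intensity units, and each column has a median of 10.1. The background correction and any offset applied before deposit are not given in the sources used here, so the size of fold changes at low intensities depends on an unknown step. A further deposited table of unnormalized values has 12 columns, a signal and a detection p-value for each of 6 arrays. Its headers name chip positions that no label ties to a sample, so these 12 columns were not used here. The design written before the data were examined had named that table, with background correction and normalization by limma's neqc function and a filter on detection p-values. The processed table, planned as an alternative, took its place.

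Deposited intensities were taken to log2 with no offset. Of 47323 probes, 30113 have 1 gene symbol in the platform annotation, 8 have several and 17202 are not listed there and stay unnamed here. No gene was named from a probe with several symbols, and no coordinates are given. Without detection p-values, probes were kept where the deposited intensity was above 32 on at least 3 of the 6 arrays, whatever their group. This floor was chosen after seeing the distribution of the intensities and before any comparison of the groups. It is a chosen limit and not a measured background. The filter kept 15335 probes, 12535 of them named, for 9757 genes. Each gene was represented by its kept probe with the highest mean log2 intensity over all 6 arrays.

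The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no block, two-sided), with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05 on the adjusted p-value. The 37 gene lists were fixed before the data were examined. They hold 1233 entries for 1187 distinct genes, and the 33 lists with at least 5 kept members were tested with limma's camera function against all other kept genes, with a preset correlation of 0.01 and adjustment over these lists. With the preset correlation, camera judges a list against the spread between genes, so its p-values are no measure of the spread between arrays. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move, on balance, in 1 direction, and makes no comparison with other genes.

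The rule for named genes was also fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap, leaving out LOC, FLJ, KIAA, HS and open reading frame names. It adds up to 4 called members of each list with the largest changes, called members of the lists for other cell types, and a fixed set of genes reported whatever their result: CDK4, CDK6, CCND1, CCNE1, CCNE2, RB1, RBL1, CDKN1A, CDKN2A, E2F1, MKI67, CCNA2, MTOR, TFEB, LAMP1, SOD2, CDH1 and VIM. The rule gave 160 genes, from which examples are described.

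The fit was tested on simulated data with the spread of these arrays and 15335 probes, of which 200 were changed. It recovered 81% of the 2-fold changes and 41% of the changes of 0.5 on the log2 scale, and called 9 unchanged probes. In the real comparison 42.6% of kept probes were called, a far larger share than was changed in the simulation. The adjustment is less strict there, so these rates do not carry over to it. Alternatives covered the normalization, the filter, the variance model, array weights, a replicate block, leaving out each array, the probe chosen per gene, the set test and, chosen after seeing the data, an offset of 16 or 50, a floor of 16 or 64, centring on ribosomal protein probes and a shorter oxidative phosphorylation list.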

Results

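Gene expression was measured in Capan-2 pancreatic cancer cells after 72 h with PD-0332991, which inhibits CDK4 and CDK6, the kinases that drive entry into the cell cycle by phosphorylating the retinoblastoma protein. Cells given DMSO served as the control (n = 3 arrays per group). The study's title places the comparison in the context of metabolic re-programming, so the question addressed was which cell cycle and metabolic genes differed in their transcript level under the inhibitor. Each array held 47323 intensities with a median of 10.1, and 15063 of them (31.8%) were above 32. Across the kept probes, arrays correlated with r of 0.991 to 0.995 within a group and 0.962 to 0.964 between groups. These correlations are across probes, which are not independent replicates. The median SD of a probe on the log2 scale was 0.125 among the DMSO arrays and 0.095 among the PD-0332991 arrays.

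Among the gene lists, transcripts of mitosis fell the most under PD-0332991, and most of the largest rises were in genes that were dim in the control. The largest fall among genes measured on both sides was that of HMMR, a spindle-associated protein, from 1230 ± 93.2 to 99.6 ± 9.64 (mean intensity ± SD, n = 3), a log2 fold change of -3.63 ± 0.10 (SE). The mitotic kinesin KIF2C (-3.52 ± 0.16), the metal-binding protein MT2A (-3.49 ± 0.10), the mitotic kinase CDK1 (-3.45 ± 0.12) and the topoisomerase TOP2A (-3.25 ± 0.07) fell by similar amounts. CKAP2L was at least 7.73-fold lower, NEK2 at least 4.99-fold, PKMYT1 at least 4.13-fold, MND1 at least 3.1-fold and DEPDC1 at least 2.97-fold. LYNX1 rose from 73.9 ± 4.86 to 680 ± 3.13 (log2 fold change 3.20 ± 0.08) and the glutathione transferase GSTA1 from 86.6 ± 8.32 to 715 ± 35.7 (3.05 ± 0.09). The folate receptor FOLR1 was at least 7.67-fold higher, the alcohol dehydrogenases ADH1C and ADH1A at least 7.37-fold and 6.56-fold, the brush border scaffold PDZK1 at least 6.3-fold and the secreted lectin REG4 at least 5.95-fold. MS4A8 was at least 4.85-fold higher, TMEM213 at least 3.03-fold and ODAM at least 3-fold. Signed values and values with an SE alone are log2 fold changes, PD-0332991 over DMSO. A fold given as "at least" sets a group whose 3 arrays all lay below an intensity of 32 to that value. All 20 genes had an adjusted p of 0.000375 or less. Probes of near-identical genes, such as ADH1A and ADH1C, GSTA1 and its neighbour GSTA2, or the metallothioneins, can read each other's transcripts.

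In total 6534 of 15335 kept probes (42.6%) passed the threshold, 3370 higher and 3164 lower in PD-0332991, and 488 and 465 of these changed at least 2-fold. By gene, 2257 were higher and 2156 lower of 9757. The median log2 fold change over all kept probes was -0.002. Quantile normalization makes the arrays' distributions equal, so this median and the near balance of rises and falls follow largely from that step. A shift shared by most genes could not be seen. Of 2303 genes with several kept probes, 28 had probes called in opposite directions, MSMO1, STMN1, LAMP2 and ERBB3 among them, and of 1047 called genes with several kept probes 391 had a kept probe that was not called. With no filter on dim probes the counts were 1351 higher and 1172 lower, and with 50 added before log2 the 2-fold counts were 156 and 198.

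Mitotic genes fell as a group. All 68 measured members of the mitosis and G2/M list were lower (68 adjusted over the list alone), with a median log2 fold change of -2.41, or -2.14 with the 14 members that lay under the floor in a group set to it (camera, adjusted p = 3.81e-35; adjusted p = 0.149 with an estimated correlation). Cyclin A2 (CCNA2) fell from 525 ± 91.1 to 67 ± 8.2. Of 47 measured genes of E2F and DNA replication, 35 were lower and 2 higher (36 and 3 adjusted over the list alone), with a median of -0.78 (camera, adjusted p = 4.71e-11; adjusted p = 0.251 with an estimated correlation). Log2 fold changes were -2.93 ± 0.11 for the transcription factor E2F2, -2.65 ± 0.12 for the replication licensing factor CDT1, -2.41 ± 0.08 for the thymidylate synthase TYMS and -2.37 ± 0.09 for the histone chaperone ASF1B. The 2 higher members were CCNE1 and SLBP (0.48 and 0.22 on the log2 scale). SLBP was named after its value was seen, and its call ended in most alternatives: without any array except DMSO replicate 3 (adjusted p of 0.0794 to 0.121), with cyclic loess (0.0515), a trended and robust variance (0.0956), a replicate block (0.0742), the mean of its probes (0.108), 50 added (0.0632), a floor of 16 (0.0658) and no filter (0.354). E2F1 itself was dim, at 38.4 ± 21.2 and 29.1 ± 9.02, and did not pass the threshold (adjusted p = 0.546).

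The transcripts of the drug's target kinases did not pass the threshold, while those of 3 CDK inhibitors were lower. CDK4 was at 1340 ± 88.6 in DMSO and 1260 ± 60.3 in PD-0332991 (adjusted p = 0.417), CDK6 at 1250 ± 128 and 1310 ± 136 (0.635) and cyclin D1 (CCND1) at 3850 ± 228 and 4170 ± 57.7 (0.238). RB1, the retinoblastoma gene, was at 130 ± 8.54 and 110 ± 9.03 (0.0672), and passed the threshold when PD-0332991 replicate 3 was left out (adjusted p = 0.0474) and with a floor of 64 (0.0465). The CDK inhibitor p21 (CDKN1A) fell from 4750 ± 348 to 2180 ± 57.4 (log2 fold change -1.12 ± 0.08) and p27 (CDKN1B) from 526 ± 76.1 to 259 ± 10.5 (-1.01 ± 0.11). The CDK4 and CDK6 inhibitor CDKN2D (-0.97 ± 0.08) and the kinase CDK2 (-0.70 ± 0.09), both named after their values were seen, were also lower. The phosphatase CDC25A also fell (-1.07 ± 0.11), and cyclin E1 (CCNE1) rose (0.48 ± 0.09). Of the 18 measured cyclins, CDKs, CDK inhibitors and pocket proteins, 1 was higher and 6 lower (1 and 7 adjusted over the list alone), and the list was not called (camera, adjusted p = 0.0712), though it was with no filter (0.00124) and with a floor of 16 (0.0126). The probes of CCNE2, RBL1, CDKN2A, MKI67 and TFEB lay under the filter.

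**Figure D1:**
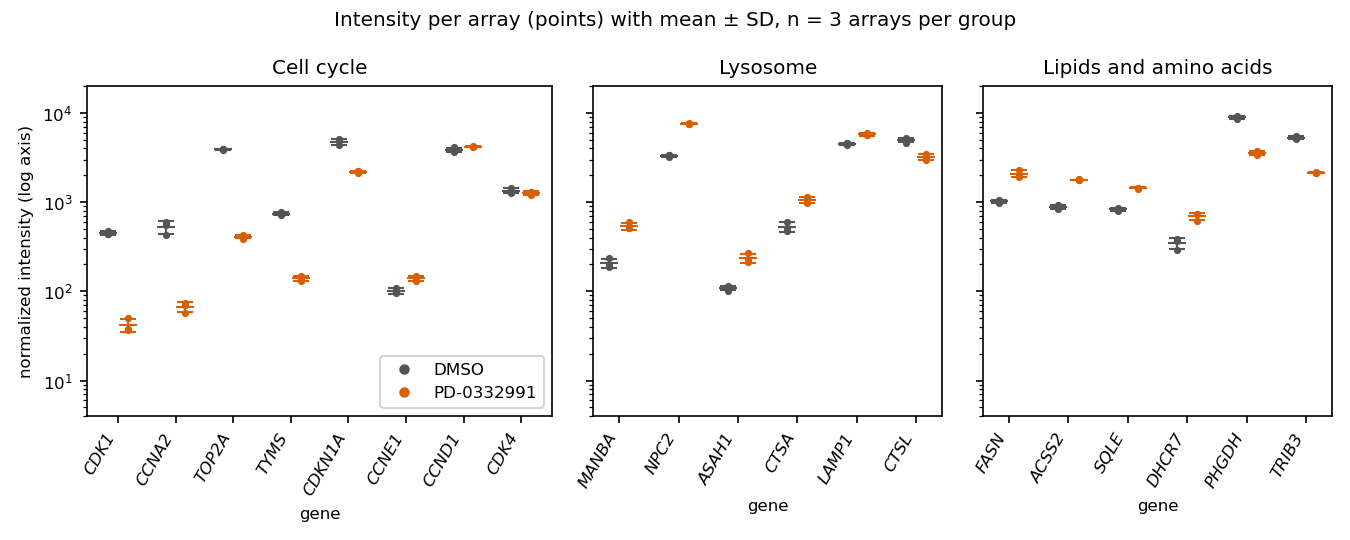
Normalized intensity (log axis) of named genes on each array, with points for the arrays and bars for the mean ± SD (n = 3 per group; DMSO grey, PD-0332991 orange). CDK1 fell from 450 to 41.6 and NPC2 rose from 3290 to 7520, while CDK4 lay at 1340 and 1260.

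Most lysosomal genes were higher. Of 50 measured members 31 were higher and 4 lower (33 and 4 adjusted over the list alone), with a median log2 fold change of 0.31 (camera, adjusted p = 7.11e-06; adjusted p = 0.123 with an estimated correlation). With no filter 10 were higher and 1 lower. Beta-mannosidase (MANBA) rose from 206 ± 25.5 to 537 ± 46.2, the cholesterol carrier NPC2 from 3290 ± 114 to 7520 ± 104, acid ceramidase (ASAH1) from 109 ± 6.47 to 235 ± 29.3 and cathepsin A (CTSA) from 529 ± 67.1 to 1060 ± 86.7. The membrane protein LAMP1 rose by 0.36 ± 0.07 on the log2 scale. The 4 lower members, named after their values were seen, were the protease CTSL (-0.62), the cholesterol transporter NPC1 (-0.44), the glucuronidase GUSB (-0.36) and the sulfatase IDS (-0.31). The call of IDS ended without PD-0332991 replicate 3 (adjusted p = 0.0608) and with the mean of its probes (0.0687). Among the 14 subunits of the proton pump that acidifies lysosomes 7 were higher and none lower (median 0.27), and among the other 36 members 24 were higher and 4 lower (median 0.36). Of 37 autophagy genes 10 were higher and 6 lower (10 and 8 adjusted over the list alone), with TP53INP1 (1.82 ± 0.10) and DEPP1 (1.67 ± 0.10) leading, and the list was not called (camera, adjusted p = 0.639).

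Part of the sterol genes were higher, and most of the amino acid response genes were lower. Of 18 measured genes of cholesterol synthesis and uptake 9 were higher, none lower and 9 not called, also when adjusted over the list alone, with a median of 0.35 (camera, adjusted p = 0.0267; adjusted p = 0.256 with an estimated correlation). With no filter 4 were higher. DHCR7, an enzyme of the last steps of cholesterol synthesis, rose by 1.00 ± 0.13 on the log2 scale, lanosterol synthase (LSS) by 0.97 ± 0.10 and squalene epoxidase (SQLE) by 0.80 ± 0.07. Of 25 measured amino acid response and ATF4 target genes 16 were lower and 1 higher, also when adjusted over the list alone, with a median of -0.40 (camera, adjusted p = 6.21e-05; adjusted p = 0.251 with an estimated correlation). With no filter 7 were lower. The higher member was ALDH18A1 (0.69), an enzyme of proline synthesis named after its value was seen. PHGDH, the first enzyme of serine synthesis, fell from 8910 ± 411 to 3570 ± 163, the pseudokinase TRIB3 from 5280 ± 211 to 2130 ± 29.6 and the amino acid transporter SLC1A4 from 278 ± 5.04 to 142 ± 9.04. Of 21 measured hypoxia genes 11 were lower and 3 higher (13 and 3 adjusted over the list alone), with a median of -0.35 (camera, adjusted p = 0.0211; adjusted p = 0.271 with an estimated correlation). With no filter 6 were lower. The demethylase KDM3A fell by 0.92, while carbonic anhydrase CA12 and adenylate kinase AK4 rose by 1.63 ± 0.10 and 0.82 ± 0.07. The remaining higher member was ADM (0.45), named after its value was seen.

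Oxidative phosphorylation genes showed a small shift. Of 69 measured members 17 were higher and 1 lower (15 and 1 adjusted over the list alone), with a median of 0.13 (camera, adjusted p = 0.0267; adjusted p = 0.6 with an estimated correlation). The count of higher members varied with the setting: 10 to 16 with 1 array left out, 11 with a replicate block, 4 with no filter, and 26 with a trended and robust variance or with 50 added. CYCS, which encodes cytochrome c, rose from 51.8 ± 7.19 to 153 ± 7.62 and NDUFC2 from 23.3 ± 8.34 to 66.5 ± 0.884, while the ATP synthase subunit ATP5MC1 rose from 1750 ± 171 to 2910 ± 231. The lower member, named after its value was seen, was NDUFA12 (-0.29), a call that ended without PD-0332991 replicate 1 (0.0625) or 2 (0.0537). The call of the list ended when DMSO replicate 1 was left out (adjusted p = 0.0841) and when CYCS and NDUFC2, which were dim in the control, were taken off the list (0.0572).

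The other metabolic lists were not called, and their members moved both ways; values in parentheses after a list's counts are camera's adjusted p. In fatty acid oxidation 11 of 23 were higher and 3 lower (camera, adjusted p = 0.0633), with the peroxisomal enzymes EHHADH and ACAA1 both at 0.76 ± 0.08. That list was called under no filter (0.00535), a floor of 16 (0.0451) or 64 (0.0189), 50 added (0.0426), the mean of all probes of a gene (0.0382) and without PD-0332991 replicate 3 (0.0389). In fatty acid synthesis 8 of 17 were higher and 3 lower (0.143): fatty acid synthase (FASN) rose from 1020 ± 36.5 to 2090 ± 190 and the acetyl-CoA synthetase ACSS2 from 885 ± 46.5 to 1780 ± 11.6, while the desaturase FADS1 fell by 0.66. In glycolysis 6 of 23 were higher and 7 lower (0.985), with PFKFB2 at 1.22 ± 0.17, ENO2 at -0.98 ± 0.13 and PFKP at -0.66 ± 0.08. The tricarboxylic acid cycle had 5 higher and 2 lower of 23 (4 and 1 adjusted over the list alone; 0.639), the pentose phosphate pathway 3 and 2 of 8 (0.639), and glutamine metabolism 4 and 4 of 9 (0.998), where the glutamine transporter SLC1A5 fell by 0.70 and the aminotransferase OAT rose by 0.78. In nucleotide synthesis 6 were higher and 4 lower of 18 (0.39), with GMPS at -1.03 ± 0.09 and CTPS1 at 0.79 ± 0.07. Mitochondrial biogenesis and the mitochondrial ribosome had 4 higher and 6 lower of 42 (3 and 5 adjusted over the list alone; 0.639). Where no count over the list alone is given here or for the lists that follow, it was the same.

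Signalling, stress and growth lists were not called either. The mTORC1 pathway list had 9 higher and 5 lower of 29 (camera, adjusted p = 0.458): the kinase MTOR rose by 0.33 ± 0.09. Called inhibitors of the pathway went both ways: CASTOR1 rose by 0.87 ± 0.08, DEPTOR by 0.45 ± 0.08 and AKT1S1 was at least 1.26-fold higher, while DDIT4 (-0.71) and SESN2 (-0.47) were lower, as was the translation repressor EIF4EBP1 (-0.75 ± 0.12). DEPTOR and SESN2 were named after their values were seen. The AKT1S1 call ended without DMSO replicate 1 (adjusted p = 0.0538) or 2 (0.057), and the SESN2 call without DMSO replicate 1 (0.0748), 2 (0.0787) or 3 (0.0554) and with a floor of 16 (0.0542). The MTOR call ended without DMSO replicate 2 (adjusted p = 0.0608) or PD-0332991 replicate 1 (0.0529), 2 (0.0714) or 3 (0.085). Antioxidant and NRF2 targets had 9 higher and 6 lower of 28 (0.57): GPX3 rose from 213 ± 30.5 to 780 ± 27 and catalase (CAT) from 295 ± 39.4 to 915 ± 84, while PRDX4 fell by 0.85. SOD2 fell by 0.33, a call that ended without PD-0332991 replicate 2 (0.0618) or 3 (0.0508). The p53 target list had 2 higher and 8 lower of 21 (0.0712; 0.0412 with no filter), with GDF15 at -0.81 ± 0.07 and RRM2B at 0.90 ± 0.12. RAS-ERK output had 2 and 7 of 23 (0.181), with the kinase MAPK6 at -0.79 ± 0.11 and the transcription factor FOSB at 1.06 ± 0.25. There were 5 higher and 4 lower of 25 in heat shock and protein folding stress (0.57), cytosolic ribosomal proteins 11 and 0 of 60 (7 and 0 adjusted over the list alone; 0.241), MYC targets and ribosome biogenesis 8 and 4 of 32 (7 and 2 adjusted over the list alone; 0.39) and histones 5 and 4 of 15 (6 and 4 adjusted over the list alone; 0.985).

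Lists of cell identity and inflammation were not called. Classical pancreatic cancer subtype genes had 17 higher and 9 lower of 38 (17 and 10 adjusted over the list alone; camera, adjusted p = 0.0801, and 0.0141 with no filter and 0.0406 with a floor of 64), led by REG4 and by TFF3, which rose from 1390 ± 194 to 3960 ± 178, while TOX3 was at least 1.65-fold lower. Basal-like subtype genes had 10 higher and 4 lower of 19 (11 and 5 adjusted over the list alone, camera adjusted p = 0.166). TNS4 was at least 1.82-fold higher, and FGFBP1, which is in both subtype lists, was at 1.16 ± 0.09. Epithelial junctions and keratins had 7 and 10 of 30 (0.599), with KRT8 rising by 0.87 ± 0.09 and DSC2 at -0.95, and E-cadherin (CDH1) stood at 6160 ± 463 and 6150 ± 166 (adjusted p = 0.998). Mesenchymal genes had 3 and 4 of 14 (0.998), and vimentin (VIM) was at 48.7 ± 3.88 and 54.1 ± 6.02 (adjusted p = 0.297). Secreted inflammatory factors of senescence had 5 higher and 10 lower of 22 (0.174): IGFBP3 fell from 9640 ± 377 to 3380 ± 95.8 and PLAUR from 658 ± 40.8 to 203 ± 19.5, IL1A was at least 1.55-fold lower, and TIMP2 rose by 1.25 ± 0.08. Interferon-stimulated genes had 10 and 13 of 35 (13 and 14 adjusted over the list alone; 0.812), with HERC5 at -1.50 ± 0.12 and IFI6 at 1.16 ± 0.10. The antigen presentation list had 4 and 5 of 20 (0.985). Written for MHC class I, it also holds class II genes, so its count and test describe neither class alone. The class II gene HLA-DMA was at 0.81 and the immunoproteasome subunit PSMB9 at -0.80 ± 0.13. The medians of glycolysis, glutamine metabolism, interferon-stimulated and mesenchymal genes differed in sign from their mean. Camera took the direction of the mean for interferon-stimulated and mesenchymal genes and of the median for glycolysis and glutamine metabolism, and fry took the other direction for glutamine metabolism and antigen presentation.

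Markers of other cell types were mostly under the filter. Of the leukocyte markers 5 were measured, with 3 higher and 1 lower (camera, adjusted p = 0.639). Lysozyme (LYZ), which is also in the classical subtype list, rose by 0.46 ± 0.07 from an intensity of 9020. CD2 rose by 0.66 ± 0.19 and ITGAM by 0.59 ± 0.20, and CD68 fell by 0.43. The CD2 call ended without any array except DMSO replicate 3 (adjusted p of 0.056 to 0.085) and with a floor of 16 (0.0512), and the ITGAM call without DMSO replicate 1 (0.117) or 3 (0.13) or PD-0332991 replicate 1 (0.114) or 2 (0.119), with cyclic loess (0.0544), array weights (0.0629) and a floor of 16 (0.0818). The CD68 call ended with the mean of its probes (0.0511). The remaining lists were too small to test. The fibroblast marker ACTA2 was at least 1.79-fold lower (1 of 2 measured), the endothelial marker PECAM1 rose by 1.12 ± 0.16 (1 of 3), the acinar gene PRSS1 fell by 1.01 from 9070 ± 600 (1 of 2), and both islet genes measured, PAX6 (-1.09 ± 0.07) and ABCC8 (-0.70 ± 0.16), fell.

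With a preset correlation 7 of the 33 tested lists were called, 3 up and 4 down. With an estimated correlation none was (limma camera; 5 had an unadjusted p under 0.05), while fry called 24 lists for movement in 1 direction and all 33 for change in either. Without the filter on dim probes 41 of the 160 named genes lost their call, among them CCNE1, LAMP1, MTOR, AKT1S1, FOSB, SOD2, LYZ, CD2, ITGAM, CD68 and ABCC8, as did SLBP, NPC1, GUSB, IDS, ADM, NDUFA12, DEPTOR and SESN2 of those named later.

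**Figure D2:**
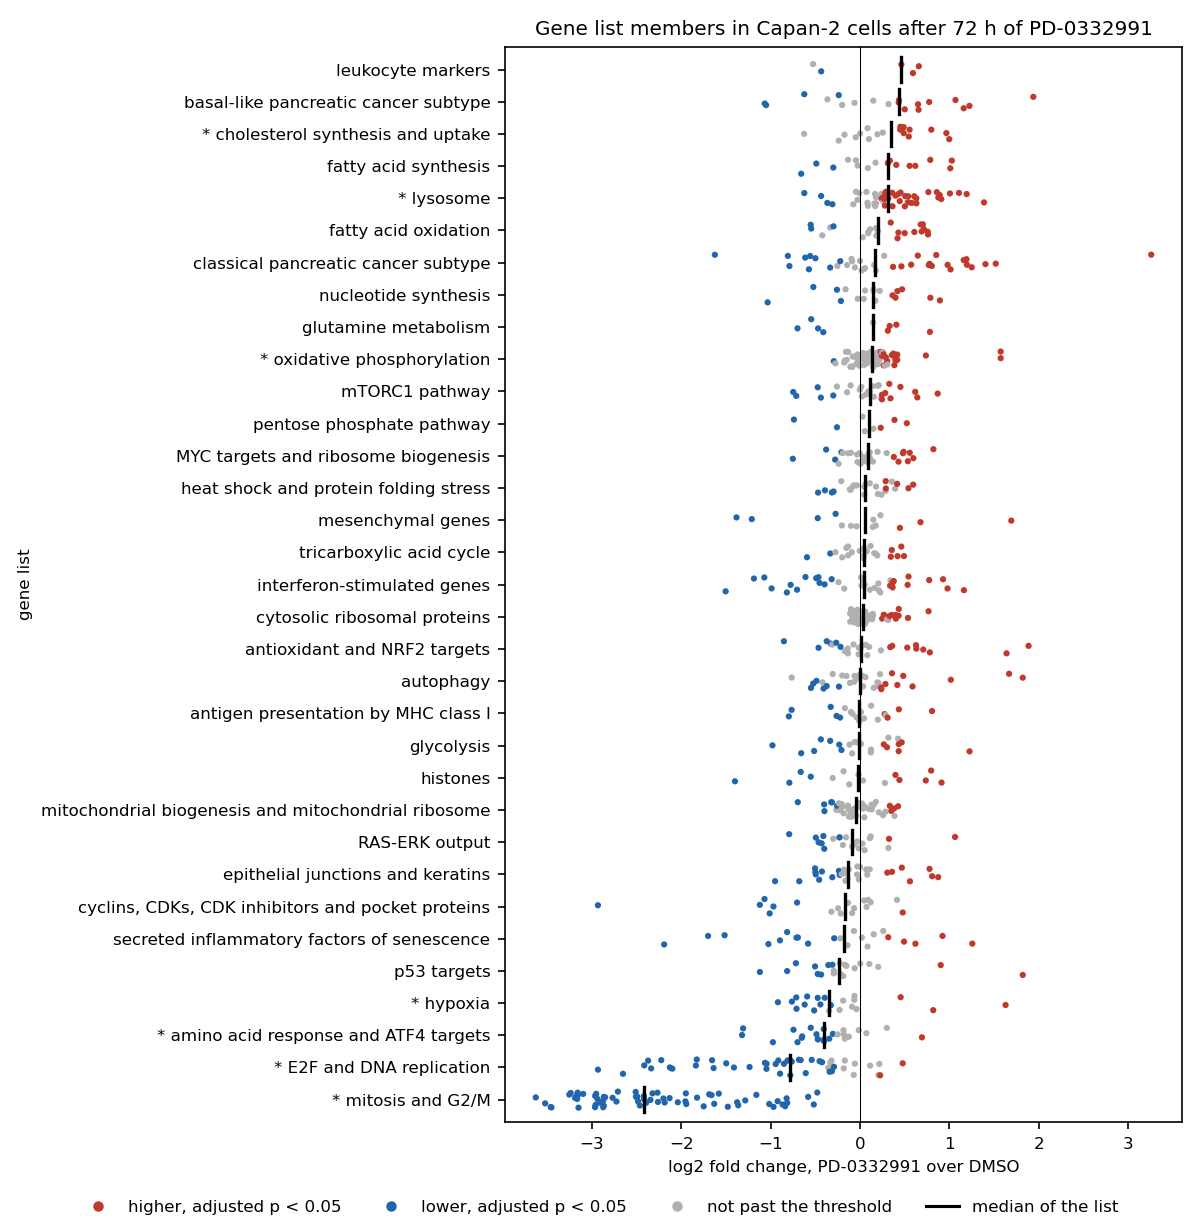
Log2 fold change (PD-0332991 over DMSO, x axis) of each measured member of the 33 tested lists (y axis, ordered by median), with 1 point per gene, red for called higher, blue for called lower and grey for not called, a black bar for the median and an asterisk for the lists called by camera. The mitosis list lies farthest left, with a median of -2.41, and the lysosome list at 0.31.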

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

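The offsets of 16 and 50, the floors of 16 and 64, the centring on ribosomal protein probes and the shorter oxidative phosphorylation list were chosen after seeing the data. Of 627 gene list tests under an alternative, 564 kept the direction and their side of the threshold. That count includes the 33 tests under a trended and robust variance, which camera was not given, so they could not change. Only 7 of the 33 lists were called in the main test, so most kept results are uncalled lists that stayed uncalled. The cause of the changes below was not tested. Leaving out the filter adds dim probes both to the adjustment and to the variance that eBayes shares between probes. These parts were not separated. Without the filter 1351 probes were higher and 1172 lower, and 2127 of these 2523 probes were also called with it. The members called then were 81 higher and 159 lower over all lists together: E2F and DNA replication 0 higher, oxidative phosphorylation 4 higher and 0 lower, lysosome 10 and 1, cholesterol 4 higher, ATF4 targets 7 lower and hypoxia 6 lower. Fatty acid oxidation (adjusted p = 0.00535), p53 targets (0.0412), the classical subtype (0.0141) and cyclins and CDKs (0.00124) became called without it, and glycolysis, interferon-stimulated genes and antigen presentation turned direction (all 0.971). With 16 added, 302 probes were higher at 2-fold or more, and with 50 added 156 higher and 198 lower. Fatty acid oxidation was called with 50 added (0.0426), with a floor of 16 (0.0451) or 64 (0.0189) and with the mean of all probes of a gene (0.0382). Cyclins and CDKs were called with a floor of 16 (0.0126) and the classical subtype with a floor of 64 (0.0406). Uncalled lists turned direction as follows: glutamine metabolism and mesenchymal genes with array weights (both 0.999), with 16 added (both 0.997), with 50 added (both 0.949) and with a floor of 64 (0.829 and 0.729), antigen presentation with a floor of 64 (0.897) and glutamine metabolism with ribosomal centring (0.985). Higher members of the E2F list fell to 1 with cyclic loess, the mean of all probes of a gene and a floor of 16. Oxidative phosphorylation had 26 higher and 5 lower members with a trended and robust variance, 26 and 2 with 50 added, and 2 lower with array weights. With an estimated correlation the adjusted p was 0.149 for mitosis, 0.251 for E2F and for ATF4 targets, 0.6 for oxidative phosphorylation, 0.123 for lysosome, 0.256 for cholesterol and 0.271 for hypoxia, so that all 7 calls ended. The estimated correlation was below the preset 0.01 for lysosome (-0.004) and cholesterol (-0.038). A stronger correlation between genes is therefore not what ended the calls of lysosome and cholesterol. The unadjusted camera p of lysosome rose from 6.46e-07 to 0.00371, so the forms of the test differ in more than the correlation. The estimated correlation was above 0.01 for mitosis (0.165), oxidative phosphorylation (0.126), E2F (0.123), ATF4 targets (0.054) and hypoxia (0.023). For these lists it may have added to the loss. Oxidative phosphorylation was not called without CYCS and NDUFC2 (0.0572). By fry, which makes no comparison with other genes, lists not called by camera passed upward for autophagy (0.00357), mTORC1 (0.0209), NRF2 targets, nucleotide synthesis, ribosomal proteins and MYC targets (each 0.00781), fatty acid synthesis (0.000925), fatty acid oxidation (0.00123), the classical (0.000142) and basal-like subtypes (0.000967), heat shock (0.00415) and leukocyte markers (0.0394). They passed downward for mitochondrial biogenesis (0.0434), p53 targets (0.000154), secreted inflammatory factors (0.000925), RAS-ERK output (0.00513) and cyclins and CDKs (0.000274), while glutamine metabolism (0.639) and antigen presentation (0.674) turned direction.

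Leaving out 1 array at a time gave 2639 to 3112 probes higher and 2470 to 2863 lower, and 476 to 508 and 451 to 480 at 2-fold or more. The adjusted p ranged from 0.00569 to 0.0841 for oxidative phosphorylation, from 0.0389 to 0.0841 for fatty acid oxidation, and, with turns of direction, from 0.919 to 0.982 for glycolysis, 0.904 to 0.991 for glutamine metabolism, 0.724 to 0.991 for mesenchymal genes and 0.792 to 0.982 for histones. Higher members numbered 1 to 2 in the E2F and in the ATF4 list and 10 to 16 in oxidative phosphorylation, and lower members 0 to 2 in oxidative phosphorylation and 0 to 1 in cholesterol synthesis. Of the 160 named genes 8 lost their call in at least 1 of these fits: MTOR, SOD2, CD2, ITGAM, RPIA, AKT1S1, DUT and TAPBPL. The log2 fold change of CDH1 was 0.01 with array weights, 0 with ribosomal centring, and -0.06 to 0.05 with an array left out. Those of CDK6 (-0.01 to 0.16) and E2F1 (-0.58 to 0.1) turned direction without DMSO replicate 3. RB1 was called with a floor of 64 (-0.25, adjusted p = 0.0465), and CD68 was not called with the mean of its probes (0.0511).

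The deviations of same-numbered arrays had an r of 0.0038, 0.0535 and 0.019 for replicates 1, 2 and 3 (across probes), and 4 of 6 arrays correlated best with their own number, so a pairing by number is not excluded. The main fit has no block, as planned before the data were examined. With a replicate block 3097 probes were higher and 2858 lower, 488 and 461 at 2-fold or more, no list gained or lost its call, glycolysis and histones turned direction (both adjusted p = 0.982), RPIA (0.0723) and TAPBPL (0.103) lost their call, and higher members numbered 1 in the E2F list and 11 in oxidative phosphorylation. Not run were normexp without detection p-values, no background correction, another neqc offset and a filter on detection p-values in all 6 arrays, which need the unassigned table. Scale normalization was not run because the medians were already equal, and a slide block because the unused headers name 1 chip. Probes near the floor limit what can be measured, since the signal over background of these arrays is not known here.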

Other observations

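The gene families described here, the comparison of the lysosome list with 3 other lists, the comparisons between metallothioneins and the counts over other splits were chosen after the results were seen. The tests against matched random lists and with 50 added were written down before their results, when the list's median and the intensities were known. Because the families were picked for their changes, their set tests are no independent evidence, and with an estimated correlation only the aldehyde dehydrogenases stay called. Of 15 measured genes with an aldehyde dehydrogenase name, 13 were higher and none lower, with a median log2 fold change of 0.69. Camera gave an adjusted p of 2.08e-06 over 5 families, and 0.0283 with an estimated correlation. The lysosome list, adjusted over 33 lists, lost its call there with a smaller unadjusted p (camera, 0.00371) than the 0.00566 of the aldehyde dehydrogenases. Most of this family oxidise aldehydes to acids, but ALDH18A1, an enzyme of proline synthesis, is also counted. ALDH1A1 had a geometric mean intensity of 28.1 in DMSO and 137 in PD-0332991 (log2 fold change 2.28 ± 0.15, with 2 of the 3 DMSO arrays under the floor of 32, so its size is uncertain), ALDH3A1 at 1730 and 3090 (0.84 ± 0.08) and ALDH4A1 at 69 and 200 (1.53 ± 0.14). Of 16 genes with a glutathione S-transferase name 9 were higher and 2 lower (camera, adjusted p = 0.0073, and 0.085 with an estimated correlation), with GSTK1 at 1.26 ± 0.08. The lower members were GSTO2 (-0.78) and the pseudogene GSTTP2 (-0.57). Of 7 UGT1A glucuronosyltransferases, which share exons so that probes can read several, 6 were higher and 1 lower (0.00256; 0.085). Among clustered core histones 11 of 28 were higher and 2 lower (0.0125; 0.209), with H4C3 at -1.40 ± 0.14. Further name patterns had been looked at before these 5 families were chosen, and the adjustment does not cover them. Without the filter 9 aldehyde dehydrogenases of 19, 6 transferases, 5 glucuronosyltransferases and 5 histones were called higher. With a floor of 16, 12 of 18 aldehyde dehydrogenases were higher and 1 lower, and with 1 array left out 10 to 13 were higher. With cyclic loess the counts were equal in all 5 families, and with ribosomal centring in all but the transferases (9 and 3).

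The rise of the lysosome list may be technical or biological. Its median lay at percentile 100 among 10000 random lists matched on mean expression, whose highest median was 0.22, which argues against a bias with intensity. A loss of cell cycle transcripts that lifted every other gene through the scaling would raise other lists by about as much. The upper quartiles of the ribosomal protein, tricarboxylic acid cycle and mitochondrial biogenesis lists were at most 0.19, below the lysosome median of 0.31, which argues against such a lift as the whole cause. Whether the transcripts rose per cell stays open, as these arrays hold no measure of RNA per cell. No biological explanation was tested, and the set call ended with an estimated correlation (adjusted p = 0.123).

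Most of the largest rises started from low intensities, where log2 without an offset could stretch small differences. LYNX1 and GSTA1 did not start under the floor of the filter: their mean intensities in DMSO were 73.9 and 86.6. With 50 added before log2, 10 of the 10 genes were still called at 2-fold or more, with log2 fold changes of 1.26 to 2.56. LYNX1 (2.56) and GSTA1 (2.49) had the highest values, and the genes that started under the floor had 1.26 to 2.19. For these 10 genes this argues against the missing offset as the whole cause. They were picked for their rise and their intensities were known, so the outcome was largely foreseeable. Over all kept probes, the rises called at 2-fold or more went from 488 to 156 with this offset. The size of each rise stays open, because the authors' background correction is not given in the sources used here. No biological explanation was tested.

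All 4 measured metallothioneins fell, with a median log2 fold change of -1.93, or -1.73 with MT1F at the floor. Camera gave an adjusted p of 0.00033 over the 5 families, and 0.085 with an estimated correlation. With no filter 4 of 10 were called lower and the median was -0.56. With 50 added the median was -1.33. The log2 fold change of MT2A minus that of MT1X was -1.99 (SE 0.11), and this pair holds the extremes of the 3 values above the floor. That difference does not decide whether all 4 probes read a single transcript. Probes of 1 transcript can differ in fold change where their backgrounds differ, and the background step is not known here. All 3 pairs among MT2A, MT1E and MT1X differed by more than 2 SE. MT1F lay under the floor on all PD-0332991 arrays, so its log2 fold change is only known to be -1.46 or lower, and whether its probe reads the transcript of MT1E (-1.95 ± 0.17) cannot be told. Cross-hybridisation, whole or partial, stays open for all, and no biological explanation was tested.

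The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and in each count 1 of the 10 splits, the real one, gave a result as large. The real split called 6534 probes against at most 0 for the others (limma; at most 274 at an unadjusted p under 0.05, against 7840), and 953 at 2-fold or more against 0. It called 7 gene lists against at most 5. Each other split called at least 2 lists while calling no probe, so a call by camera with a preset correlation does not need any called probe. The lists they called were all among the 7, the mitosis list in 9 splits, E2F and lysosome in 8, ATF4 in 5, oxidative phosphorylation in 3 and hypoxia in 1. Each of these splits leaves 2 of 3 arrays of a group together, so part of the treatment difference remains in it. The rest of that difference lies within the sides of the split, where it widens the spread and holds down the probe calls. The 0 called probes are therefore no measure of what chance would give.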
